A study of Mus musculus with 2 samples.

How the data were processed

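RNA of plasmacytoid dendritic cells (pDC) from mouse bone marrow was measured on 2 single-colour expression arrays, 1 labelled wild type and 1 labelled Mtg16 knockout. Per the labels' protocols, cells of other lineages were first removed with antibodies to CD19, Tcrb, Ter119 and NK1.1. The CD11c-positive, Bst2-positive cells were then sorted into Trizol, and total RNA was biotin-labelled with a whole-transcript kit. No granulocyte antibody is named in that depletion, so granulocytes would be removed only by the CD11c and Bst2 gate.

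The deposited values are probe set intensity values on a linear scale, from 4.1 to 28950.9 on the wild-type-labelled array and from 4.3 to 21952.3 on the knockout-labelled array. The submitters' processing notes name GCRMA, a background correction and summary method that usually gives log2 values; its version, its settings and how the values became linear are not given in the sources used here. The 2 arrays do not share 1 distribution. The upper quartile was 69.0 on the wild-type-labelled array and 57.5 on the knockout-labelled array, while the medians were 24.1 and 27.1. The values as deposited were therefore not equalised between these 2 arrays by quantiles. No detection calls were used here.

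The log2 of each deposited intensity was taken, with no pseudocount. Of 35556 probe sets, 21789 name 1 gene in the platform annotation, 1621 name several and 12146 are unnamed here. Gene symbols were checked through Entrez identifiers in a RefSeq gene table of assembly GRCm38.p6, where 21698 of the single-gene probe sets matched and 0 symbols changed. Probe sets naming 1 gene were averaged per gene, which gave 19938 genes, 999 of them with more than 1 probe set. Probe sets that name several genes were left out of every gene value, so that Gapdh, the alpha and beta globins and Ly6c2 have none. The expression floor was the median of all probe set values of both arrays (log2 4.68, intensity 25.7), and a gene was kept if the higher of its 2 values reached it, which left 11749 genes.

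With 1 array per genotype there is no estimate of the spread between mice. No p-value, standard error or replicate check can be given for any difference, and the number of arrays limits the precision. Differences are log2 values of the knockout-labelled array minus the wild-type-labelled array, and a fixed size of 2-fold describes this pair of arrays only. Where 1 of the 2 values of a gene lay below the floor, a fold is given as a lower bound counted from the floor. Counts at 2-fold and list medians use the measured values. A partial view of measurement spread came from the 523 kept genes with exactly 2 probe sets, whose differences had a median SD of 0.22 between probe sets and a 90th percentile of 0.81. This covers probe differences within the same 2 samples, not variation between animals.

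A total of 26 gene lists, the floor, the size threshold and the rule for named genes were fixed before the data were examined. For each list the median difference of the members above the floor was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called apart below the 2.5th or above the 97.5th percentile with at least 3 members. For 26 lists of independent genes this gives about 1.3 by chance, but members of a list can vary together. The named genes were the ETO, E and Id proteins, the 12 largest differences each way among genes with a standard symbol (no predicted genes, small RNAs, olfactory or vomeronasal receptors, Rik symbols or antigen receptor segments), the 2 highest and 2 lowest members of each list, 8 pDC and cDC genes, the sex-linked transcripts, and any of the 10 nearest measured genes on each side of Cbfa2t3 that were at least 2-fold apart.

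The alternatives were no floor, a floor at the 75th percentile, quantile normalization, centring each array on its median, removal of the intensity trend (lowess of the difference on the mean log2 value over all genes, fraction 0.3, 3 iterations), the brightest probe set per gene, a pseudocount of 16 on the linear scale, sizes of 1.5-fold and 3-fold, the mean in place of the median, matching in 5 bins, and no matching. Centring moved the median difference of the kept genes from -0.22 to 0.03, trend removal to 0.01 and quantile normalization to -0.05, so list results are given both as deposited and with the trend removed.

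The scripts were tested on simulated data made from the wild-type values of 19938 genes, with a known smooth trend and independent noise of a chosen size. Real genes vary together and the spread between mice is unknown. The rates below therefore check the scripts and do not carry over to the measured arrays. Of 50 genes lowered by 2 on the log2 scale, 100% passed 2-fold with either scale. Of 50 genes raised by 2, 88.0% passed as deposited and 100% after trend removal, and of 50 raised by 1.5, 44.0% and 96.0%. Of 10969 genes with no change, 4.96% passed as deposited and 0.41% after trend removal. Of 100 simulated lists of 15 genes with no shift, 4 were called apart, and of 100 shifted by 0.8, all 100 were. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used.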

Results

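Gene expression was measured in plasmacytoid dendritic cells (pDC), the dendritic cells specialised in type I interferon secretion, sorted from the bone marrow of C57BL/6 mice. The sample on 1 array was labelled wild type and that on the other Mtg16 knockout, with median intensities of 24.1 and 27.1 over all probe sets. Mtg16 is the protein of the gene Cbfa2t3, a corepressor of the ETO family that binds E proteins, the basic helix-loop-helix transcription factors on which pDC depend. The comparison addresses how its loss alters E protein activity and the choice between dendritic cell lineages. Each genotype had 1 array, so every value below is a single measurement without a replicate error, and no difference could be tested. All differences are log2 intensities of the knockout-labelled array minus the wild-type-labelled array.

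The knockout-labelled array had far more genes with lower values than with higher values. Of 11749 genes above the expression floor, 1819 were at least 2-fold lower and 165 at least 2-fold higher as deposited, so that 91.7% of the genes apart were lower. With values below the floor raised to it, 1763 were lower and 98 higher. The split depended on scaling: it was 990 lower and 304 higher after quantile normalization, 1125 and 543 after centring, and 732 and 416 after removal of the intensity trend. The median difference was -0.78 over the brightest 1175 genes above the floor and 0.38 over the dimmest 1175. Of the 1819 lower genes, 687 were also at least 2-fold lower with the trend removed, and of the 165 higher genes, 114 were also at least 2-fold higher. The log2 values of the 2 arrays correlated with r = 0.938 across all 35556 probe sets, which are not independent replicates.

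**Figure D1:**
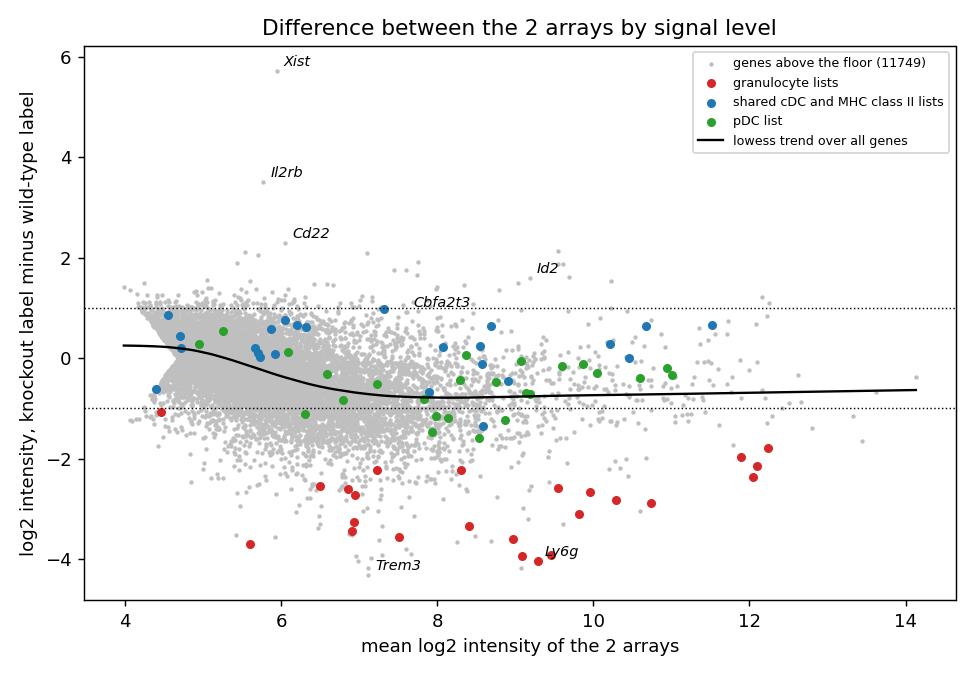
Difference between the arrays (log2 intensity, knockout label minus wild-type label) against the mean log2 intensity of the 2 arrays for 11749 genes above the floor. Each point is a gene, the black line is the lowess trend over all genes and the dotted lines mark 2-fold; the granulocyte genes (red) lie far below the trend, and most shared cDC and MHC class II genes (blue) lie above it.

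The targeted gene did not show a loss of signal. Cbfa2t3 was 1.88-fold higher on the knockout-labelled array (log2 8.06 against 7.15, difference 0.91), and passed 2-fold under the other scalings (1.16 to 1.68). Both of its probe sets were higher as deposited, by 1.06 and 0.77. The labels do not say which exons were removed, and a probe set over retained exons does not check the deletion. The genotype therefore rests on the sample labels, and the arrays are called by their labels throughout. Of the other ETO family members, Cbfa2t2 differed by -0.38 and Runx1t1 lay below the floor on both arrays, at 3.89 for the wild-type label and 4.11 for the knockout label. The ETO list had only 2 members above the floor (median 0.27; 0.68 with the trend removed), too few to be placed.

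Among the E proteins and their Id antagonists, Id2 stood out. Id2, an inhibitor of E protein binding to DNA that conventional dendritic cells express, was 3.02-fold higher on the knockout-labelled array (log2 9.98 against 8.39, difference 1.59, and 2.35 with the trend removed). Tcf3, which encodes E2A, was 2.62-fold lower (difference -1.39, and -0.67 with the trend removed). Tcf4, which encodes E2-2, the E protein required for pDC, differed by -0.30 and Tcf12, which encodes HEB, by -0.27; both values turned positive with the trend removed, at 0.45 and 0.52. Id1 differed by -0.48 and Id4 by 0.14, and Id3 was below the floor on both arrays. Of the 6 members above the floor, 1 was at least 2-fold higher, 1 at least 2-fold lower and 4 within 2-fold. The median of this list was -0.29 as deposited, 0.09 after quantile normalization and 0.30 with the trend removed, and it lay at the 82.8th percentile of matched random lists.

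**Figure D2:**
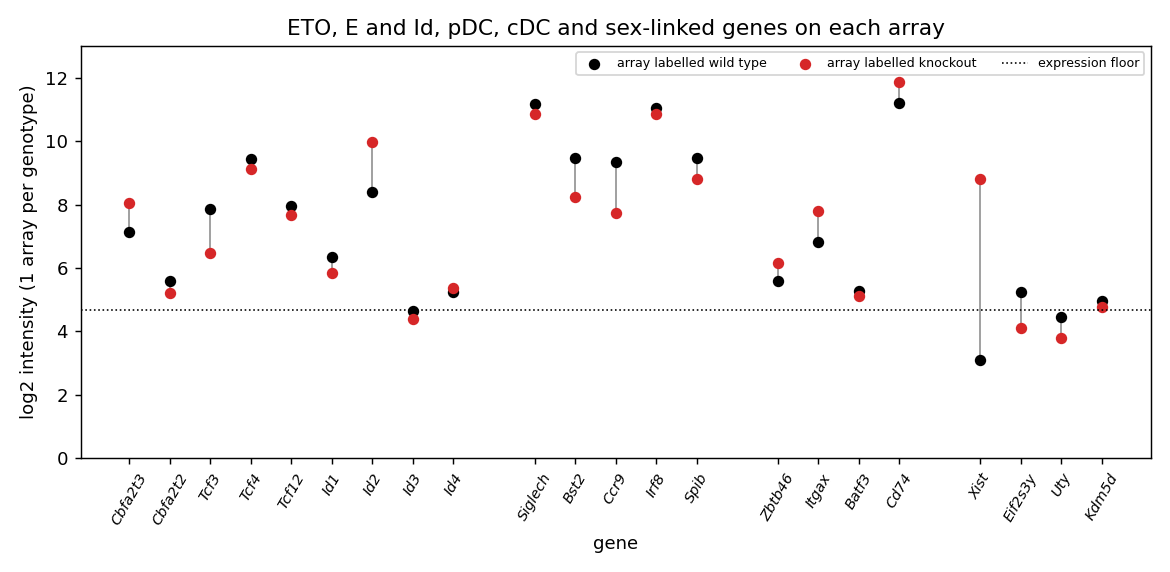
Log2 intensity of ETO, E and Id, pDC, cDC and sex-linked genes on each array (black, wild-type label; red, knockout label; 1 array each, so no error bars). The dotted line is the expression floor; Id2 was 3.02-fold higher and Xist at least 17.4-fold higher, counted from the floor, on the knockout-labelled array, while Siglech and Irf8 were within 2-fold.

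Several genes that characterise pDC were bright on both arrays. Siglech, a pDC surface lectin, was at 11.17 on the wild-type-labelled and 10.84 on the knockout-labelled array, and Irf8, a transcription factor of the dendritic lineages, was at 11.04 and 10.85. The small differences of both turned positive with the trend removed (0.38 and 0.52), and that of Irf8 also after quantile normalization (0.11) and centring (0.06). Of 25 pDC genes above the floor, 6 were at least 2-fold lower as deposited, 0 at least 2-fold higher and 19 within 2-fold. The lowest were Ccr9, a chemokine receptor of mature pDC, at -1.59, and Havcr1 at -1.47. Bst2, the surface marker used in the sort, differed by -1.23, and Spib, a pDC transcription factor, by -0.69 (0.07 with the trend removed). At the other end lay Klk1b27 at 0.54 and Rpgrip1 at 0.28. The list median was -0.44 as deposited, -0.02 after quantile normalization, -0.19 after centring and 0.28 with the trend removed, at which point all 25 members were within 2-fold. The list was not apart from matched random lists (89.3rd percentile as deposited, 96.0th with the trend removed). The 12 genes of endosomal nucleic acid sensing and its route to interferon gave a median of -0.71 (44th percentile; 0.05 with the trend removed). In that list Slc15a4, a lysosomal transporter needed for Toll-like receptor signalling in pDC, differed by -1.52 (-0.79 with the trend removed). Myd88, the receptor adaptor, differed by -1.35 (-0.57 with the trend removed). Tlr12 differed by 0.25 and Irak1 by -0.27 (0.24 after quantile normalization, 0.40 with the trend removed). Of the 12 genes, 4 were at least 2-fold lower as deposited and 0 with the trend removed.

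Genes shared by conventional dendritic cells (cDC) and genes of MHC class II presentation were higher on the knockout-labelled array than genes of like level. The 15 shared cDC genes had a median of 0.23 (99.7th percentile; 0.40 to 0.66 under the other scalings), with 12 members above 0. Itgax, which encodes CD11c, was 1.97-fold higher (0.98), Ccr7, a migration receptor, 1.70-fold (0.77) and Zbtb46, a cDC transcription factor, differed by 0.58. Csf2rb, a receptor subunit for GM-CSF, went the other way at -1.36. Cd86, a costimulatory ligand, lay at 4.71 and at 4.10, below the floor, and counted from the floor was at least 1.02-fold lower. The 10 MHC class II genes had a median of 0.22 (99.2nd percentile; 0.46 to 0.69 under the other scalings), with 8 above 0. Cd74, the invariant chain, differed by 0.67 and H2-Eb2, below the floor on the wild-type-labelled array, was at least 1.23-fold higher, against -0.66 for H2-Oa and -0.45 for H2-DMa, both of which turned positive with the trend removed (0.12 and 0.32). As deposited, no gene of either list passed 2-fold upwards, and with the trend removed 6 shared cDC and 4 MHC class II genes did. The B lineage and the monocyte and macrophage lists, whose cells also express MHC class II, lay as high (99.9th and 99.2nd percentiles; 0.46 and 0.52 with the trend removed). Neither the cDC nor the MHC class II list was apart when the random lists were not matched on expression (97.2nd and 94.5th percentiles). Itgax encodes a marker of the sort itself.

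The genes that separate the cDC subsets did not move as blocks. The 14 genes of the XCR1-positive subset, cDC1, had a median of -0.31 (46.8th percentile; 0.002 with the trend removed), with 2 at least 2-fold higher and 3 at least 2-fold lower. With the trend removed 2 were at least 2-fold higher and 0 at least 2-fold lower. Ifi205, an interferon-inducible gene below the floor on the wild-type-labelled array, was at least 3.24-fold higher and Clec9a, a receptor for dead cells, 2.24-fold higher. Cxcr3, a chemokine receptor, was 3.08-fold lower and Wdfy4 2.10-fold lower, differences of -0.88 and -0.37 with the trend removed. Batf3, the cDC1 transcription factor, differed by -0.14 (0.11 after centring). The 14 genes of the SIRPa-positive subset, cDC2, had a median of -0.77 (18.8th percentile), with 4 at least 2-fold lower and 0 higher. With the trend removed the median was -0.0004 (51.4th percentile), with 2 at least 2-fold higher and 3 at least 2-fold lower. Without matching on expression the list was apart (percentile 1.19). Cd4 differed by -1.95 and Itgam, which encodes CD11b, by -1.90, while Klf4 differed by 0.99 and Cd209a by 0.76 (1.35 and 1.54 with the trend removed). Granulocytes express Itgam too. Xcr1, Rab7b and Gcsam of the cDC1 list lay below the floor on both arrays, so its median leaves them out. The same holds for Clec4a4, Esam and Epcam of the cDC2 list.

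Of the 26 lists, the 2 of granulocyte genes had the lowest medians, and all of their members above the floor were lower on the knockout-labelled array. All 18 neutrophil genes were at least 2-fold lower (median -2.78, below all 10000 random lists; -2.07 with the trend removed), from Ly6g at -4.05 (16.5-fold lower) and the gelatinase Mmp9 at -3.94 to S100a9 at -1.97 and the granule gene Ngp at -1.79. Their levels on the wild-type-labelled array were among the brightest measured: Ngp was at 13.13 and S100a9 at 12.88, and on the knockout-labelled array they were still at 11.34 and 10.91. All 6 genes of basophils, mast cells and eosinophils above the floor were lower too (median -2.91; -2.29 with the trend removed). Prg2, the eosinophil major basic protein, differed by -3.57 and Hdc by -2.22. Mcpt8, a basophil protease, and Cpa3 were below the floor on the knockout-labelled array, and counted from the floor were at least 6.78-fold and 1.24-fold lower. The monocyte and macrophage list did not follow. Its median was -0.04 over 17 genes, at the 99.2nd percentile of matched lists, its mean was -0.24, and its median turned positive under the other scalings (0.20 to 0.52). The monocyte call was lost with the mean (96.5th percentile) and without matching (77.7th). In it F13a1 differed by -2.94 and Lyz2, which granulocytes also express, by -1.72, while Fcgr1 differed by 0.95 and Marco, a scavenger receptor below the floor on the wild-type-labelled array, was at least 1.72-fold higher.

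**Figure D3:**
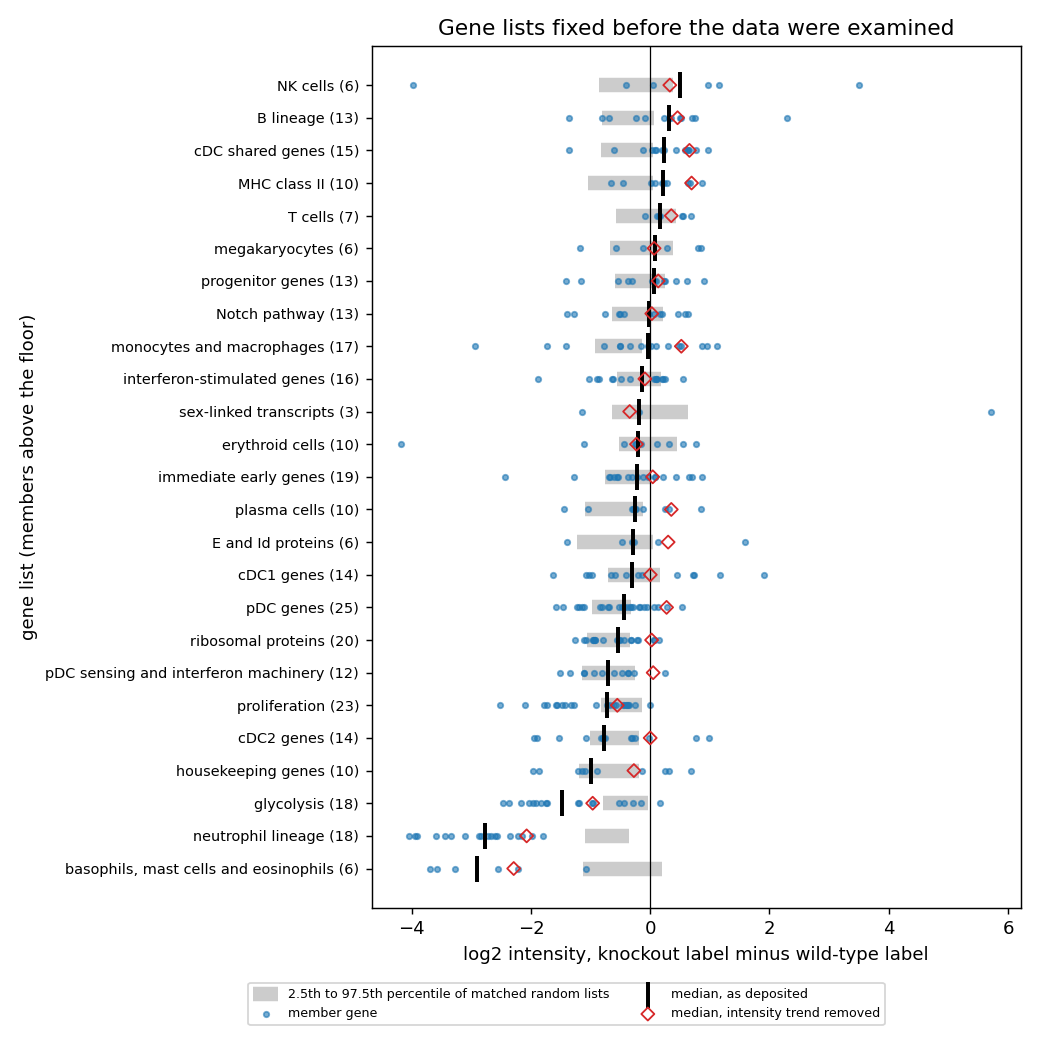
Difference between the arrays (log2 intensity, knockout label minus wild-type label) for the members above the floor of each gene list with at least 3 such members. Blue points are genes, black bars list medians as deposited, open red diamonds medians with the intensity trend removed, and grey bands the range of matched random list medians outside which a list was called apart; the neutrophil median (-2.78) and the basophil, mast cell and eosinophil median (-2.91) lie farthest from their bands.

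Glycolytic genes were lower on the knockout-labelled array, together with the granulocyte genes. Of 18 members above the floor, 11 were at least 2-fold lower and 0 at least 2-fold higher (median -1.48, below all 10000 random lists). With the trend removed 8 were at least 2-fold lower and 16 lay below 0 (median -0.96). Aldoa, the aldolase of the pathway, was 5.50-fold lower and the hexokinase Hk3 5.14-fold lower, whereas Hk1 differed by -0.16 (0.09 to 0.63 under the other scalings) and Pfkm by 0.16. Of 23 cell cycle genes, 10 were at least 2-fold lower and 0 higher, with a median of -0.72 at percentile 8.11 as deposited. The list was apart with the trend removed (median -0.55, 6 genes at least 2-fold lower and 17 below 0). It was also apart after quantile normalization, with the floor at the 75th percentile, with the mean and without matching. The mitotic kinase Plk1 was 5.71-fold lower and the replication helicase subunit Mcm5 4.26-fold lower, against -0.26 for Mki67 (0.52 with the trend removed) and 0.003 for Top2a (-0.15 with the trend removed). The neutrophil median of -2.78 stands beside both lists.

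The 12 largest differences each way were named by rule. The 12 lowest were Trem3, Ifitm6, Car1, Ly6g, S100a6, Nkg7, Mmp9, Dgat1, Lrg1, Ctsg, Chil1 and Ms4a3, from 19.9-fold lower for Trem3 to -3.80 on the log2 scale for Ms4a3. With the trend removed they were 12.1-fold to 8.18-fold lower. Ly6g, Mmp9 and Ctsg belong to the neutrophil list. The 12 highest by measured difference were Xist, Il2rb, Cd22, Cd209e, Cxcl9, Rgs18, Ifi205, Ifi203, Id2, Kcnj14, Ly86 and Ferd3l. Il2rb, the beta chain of the interleukin 2 receptor, was at 7.52 against 4.02. Cd22, an inhibitory lectin of B cells, was 4.90-fold higher, the chemokine Cxcl9 4.14-fold, and Rgs18, a regulator of G protein signalling, 3.76-fold. Ifi203 was 3.36-fold higher and Ly86, a partner of the Toll-like receptor relative CD180, 2.92-fold. Xist, Il2rb, Cd209e, Ifi205, Kcnj14 and Ferd3l lay below the floor on the wild-type-labelled array. Counted from the floor, they were at least 17.4, 7.12, 3.73, 3.24, 2.22 and 1.24-fold higher, in that order, so that the places of Kcnj14 and Ferd3l among the 12 rest on background.

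The arrays also differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome of female mice, was at 8.80 on the knockout-labelled array and at 3.09, below the floor, on the wild-type-labelled array. The Y-linked Eif2s3y was lower on the knockout-labelled array (4.10, below the floor, against 5.24). Uty was below the floor on both arrays, and Kdm5d differed by -0.19 (0.06 after centring). The list median over the 3 members above the floor was -0.19 (21.3rd percentile; 0.06 after centring, -0.34 with the trend removed) and its mean, which Xist sets, was 1.46 (99.8th percentile). Any effect of sex is confounded with genotype here.

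Of the markers of other cells, the B lineage list had a median of 0.32 over 13 genes (99.9th percentile, and 0.46 with the trend removed). Cd22 differed by 2.29, Cd79a by 0.75, Fcrla by -1.36 and Blnk by -0.80. Ms4a1, Ebf1, Bank1, Rag1 and Rag2 lay below the floor on both arrays and Cd19 had no single-gene probe set, so the median leaves them out. Spib is in both this list and the pDC list, so not every member is particular to B cells. The natural killer cell list had a median of 0.50 over 6 genes (percentile 99.1, and 0.33 with the trend removed). That call was lost with the trend removed (87.8), after quantile normalization (93.3), without a floor (81.0), with the mean (96.6) and with a pseudocount of 16 (97.3). Il2rb, from below the floor, was at least 7.12-fold higher, Klrd1 differed by 1.15, Nkg7 by -3.98 and Ccl5 by -0.41. Ncr1, Klrb1c, Klra8, Klre1, Klrc1, Gzma, Gzmb and Eomes lay below the floor on both arrays. The plasma cell list had a median of -0.25 (92.3rd percentile; 0.11 after quantile normalization, 0.35 with the trend removed), with Jchain at 0.85, Sdc1 at 0.31, Slpi at -1.44 and Creld2 at -1.05. T cell genes had a median of 0.16 over 7 genes (77.2nd percentile; 0.35 with the trend removed) and were apart after quantile normalization (0.40, percentile 97.54) and with the mean (98.3), with Bcl11b at 0.69 and Cd6, from below the floor, at least 1.25-fold higher, against Lat at -0.09 (0.16 after centring) and Il7r at 0.11. Erythroid genes had a median of -0.20 (21.6th percentile; 0.05 after centring, -0.23 with the trend removed), with Car1 at -4.17 and Car2 at -1.11. Alas2 and Hemgn were below the floor on the wild-type-labelled array and at least 1.02-fold and 1.06-fold higher counted from it. Megakaryocyte genes had a median of 0.08 (75.2nd percentile; 0.07 with the trend removed), with Itgb3 at -1.18, Itga2b at -0.58, Treml1 at 0.81 and Ppbp, from below the floor, at least 1.61-fold higher.

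The remaining lists lay within the range of matched random lists as deposited. Interferon-stimulated genes had a median of -0.14 (59.9th percentile; 0.11 after centring, -0.09 with the trend removed), with Stat2 at -1.89 and Oas3 at -1.02 against Oas2 at 0.25 and Ifih1, from below the floor, at least 1.23-fold higher. Notch pathway genes had a median of -0.01 (80th percentile; 0.23 after centring, 0.03 with the trend removed), with Notch1 at -1.39 and Gfi1 at -1.28 against Dtx1 at 0.59 and Hes1, from below the floor, at least 1.41-fold higher. Progenitor genes had a median of 0.06 (83.1st percentile; -0.01 after quantile normalization, 0.14 with the trend removed), with Lmo2 at -1.16 and Mycn at 0.89. Cd34, below the floor on the knockout-labelled array, was at least 2.33-fold lower, and Meis1, below it on the wild-type-labelled array, at least 1.3-fold higher. Immediate early genes had a median of -0.23 (77.6th percentile; 0.02 after centring, 0.04 with the trend removed), with Dusp1 at -2.43 and Ier2, below the floor on the knockout-labelled array, at least 1.74-fold lower, against Fosb at 0.87 and Egr3 at 0.70. Ribosomal protein genes had a median of -0.54 (79.3rd percentile; 0.02 with the trend removed), with Rpl8 at -1.26 and Rplp1 at -1.11 against Rpl14 at 0.14 and Rpl23 at 0.06. Housekeeping genes had a median of -0.99 (10.7th percentile; -0.27 with the trend removed; apart without matching, percentile 0.35), with Pgk1 at -1.97 and Hprt at -1.86 against B2m at 0.68 and Tfrc at 0.31. Of the 20 nearest measured neighbours of Cbfa2t3, 3 were at least 2-fold lower, Chmp1a at 6.53 against 8.53, Cdt1 at -1.86 and Piezo1 at -1.17. With the trend removed 2 were, and Piezo1 differed by -0.60. At least 2-fold higher were 0 (median -0.41, and -0.20 with the trend removed). Over all genes above the floor a like share was at least 2-fold lower as deposited, 1819 of 11749.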

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

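The tests of a single scale factor and of dilution by granulocyte RNA were chosen after the results were seen; the other tests were written down before their values were computed. Probe sets outside the gene comparisons carried differences too. Of 1153 probe sets above the floor that name several genes, 66 were at least 2-fold higher and 132 at least 2-fold lower on the knockout-labelled array. Of 5522 unnamed probe sets, 763 were at least 2-fold higher and 812 at least 2-fold lower.

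The first pattern is the lower level of granulocyte genes on the knockout-labelled array. A difference that follows signal level alone is argued against as the whole cause. The 24 members of both granulocyte lists kept a median of -2.07 with the trend removed (quartiles -2.78 and -1.63, all 24 below 0), against -2.78 as deposited. The fitted trend is small beside these differences. The values thus restate where the lists lay among matched random lists and are not separate evidence. Granulocytes in the wild-type-labelled sample would bring further neutrophil transcripts. A second list of 30 neutrophil genes, with 26 above the floor, had a trend-removed median of -1.998 with 25 of 26 lower, as that explanation needs. Of the 26, 17 were above the floor on the knockout-labelled array as well. Neutrophil genes vary together, and the second list was read on the same 2 arrays as the first. It was therefore likely to lie low under any cause, and it does not tell the causes apart. The CD11c and Bst2 gate should remove granulocytes. On the wild-type-labelled array Elane was at 12.17 and Mmp9 at 11.06, beside Siglech at 11.17. On the knockout-labelled array Lcn2 was still at 11.02 and Mmp9 at 7.12, beside Siglech at 10.84. Granulocyte RNA on both arrays, in unlike amounts, is thus also open. An effect of genotype within the sorted cells would need those cells to express these genes at such levels. That effect, or one of the mice used, remains open and untested.

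The second pattern is the excess of lower over higher genes. A single scale factor between the arrays is argued against, because the median of the brightest 1175 genes minus that of the dimmest 1175 was -1.16 (quartiles -1.25 and -0.29 against 0.11 and 0.60). A response that depends on intensity alone should act on unnamed probe sets too, and 2606 of them with a mean log2 value of 6 or more had a median of -0.011 (quartiles -0.77 and 0.63), against -0.65 for 4664 genes. Unnamed probe sets went both ways, and they share only that cut with the genes, so an intensity-dependent difference stays open and its removal may take out real differences as well. RNA quality, sex, genotype and granulocyte RNA on the wild-type-labelled array remain open and were not tested. Without the genes of the granulocyte and monocyte lists 1768 genes were still lower. Other genes that granulocytes express stay in that count, so it does not decide the last of these.

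The third pattern is the higher level of Id2, shared cDC and MHC class II genes, beside which B lineage (0.46 with the trend removed) and monocyte (0.52) genes lay high too. The fitted intensity trend is below 0 for most of these 25 genes, so it runs against their higher level. Its removal could only raise their median, from 0.24 as deposited to 0.74 (23 above 0, quartiles 0.32 and 1.12). That rise is therefore no separate evidence against the trend as a cause. Dilution by granulocyte RNA should raise all dendritic cell genes alike; the median of these genes minus that of 25 pDC genes was 0.46 (95% bootstrap interval over genes 0.04 to 0.97), which does not decide it, because the lists were picked for being higher and co-regulated genes are not independent. More conventional dendritic cells in the knockout-labelled sample could be another source. The 28 subset genes of cDC1 and cDC2 above the floor had a median of -0.0004 with the trend removed (quartiles -0.41 and 0.50). Members went both ways, which does not decide it. Xcr1, Clec4a4 and Esam are not among the 28, because they lay below the floor on both arrays. B cells or monocytes in the sample, which the CD19 depletion and the gate should remove, and genotype remain open and untested. Of the 18 measured B lineage genes, 13 were above the floor, but Ms4a1 and Ebf1 were not. Spib, among the 13, is on the pDC list too.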

How the results depend on the processing

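Of the settings here, the counts without the granulocyte and monocyte lists and those with values below the floor raised to it were chosen after seeing the data. Counts of genes apart depended on the size, the scaling and the pseudocount. The higher genes, 165 as deposited, numbered 304 after quantile normalization, 543 after centring, 416 with the trend removed, 87 with the floor at the 75th percentile and 42 with a pseudocount of 16; the lower genes, 1819 as deposited, numbered 990, 1125 and 732 under the same 3 scalings and stayed within 1.5 times under the floor and pseudocount settings. At sizes of 1.5-fold and 3-fold there were 1126 and 16 higher and 3682 and 520 lower genes. Leaving out those lists, together with the second neutrophil list, gave 164 higher and 1768 lower genes, and raising values to the floor gave 98 and 1763. Cbfa2t3, 0.91 as deposited, passed 2-fold at 1.45 after quantile normalization, 1.16 after centring and 1.68 with the trend removed. The number of lists apart was 8 as deposited and 7 to 9 otherwise. The shared cDC (0.23) and MHC class II (0.22) medians were not apart without matching on expression, at the 97.2nd and 94.5th percentiles; the neutrophil, basophil, glycolysis and B lineage lists were apart under all 10 alternatives. The monocyte list turned from -0.04 to 0.31, 0.20 and 0.52 under quantile normalization, centring and trend removal. The causes were not tested. Of 71 named genes at least 2-fold apart, 48 stayed 2-fold apart under all 3 scalings. That 0 of them changed sign was fixed in advance, because each scaling moved a gene by less than 2-fold. No paired analysis was possible because each genotype has 1 array, and for the same reason no replicate could be left out. Values below the floor rest on background and limit the ratios of dim genes.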

Other observations

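A scan of 182 gene families that share a symbol stem, each with at least 8 members above the floor, was made after the data were seen. As deposited 29 lay outside the central range of matched random lists, and with the trend removed 35. Independent genes would give about 9.1 by chance. Members of a family can vary together or share sequence, so that figure does not hold for them and the excess is not a test. Immunoglobulin kappa variable segments led the higher end: 6 of 8 were at least 2-fold higher on the knockout-labelled array as deposited and all 8 with the trend removed, with medians of 1.42 and 2.13. These segments share sequence, so their probe sets are not independent. Beside them the B lineage list lay high (median 0.32, 99.9th percentile), while the plasma cell list was not apart (-0.25, 92.3rd percentile). Collagen genes (stem Col) had a median of 0.59, with 4 of 40 at least 2-fold higher, keratin-associated proteins (Krtap) 0.51 with 0 of 14, olfactory receptors 0.52 with 6 of 60 and Sox factors 0.43 with 2 of 17. With the trend removed these medians were 0.66, 0.73, 0.44 and 0.57, with 13, 4, 6 and 1 members at least 2-fold higher. The dimmest 1175 of all genes above the floor had a median of 0.38 as deposited. A gene was kept if the higher of its 2 values reached the floor, so dim genes can enter through the array that reads higher. An offset near background can therefore not be told apart from a real rise of these 4 families. The large ribosomal subunit stem Rpl (34 members) lay high among matched lists, at percentile 99.65 as deposited and 99.81 with the trend removed. Its median was -0.28 as deposited, -0.03 after centring, 0.06 after quantile normalization and 0.42 with the trend removed. The small subunit stem Rps (30 members) was not apart, at percentiles 63.7 and 85.3. Nor was the planned ribosomal protein list, at 79.3 and 47.0.

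At the lower end stood annexins (9 members, median -1.22, 5 at least 2-fold lower), minichromosome maintenance genes of DNA replication (8 members, -1.23), dehydrogenases of the Dhrs stem (9 members, -1.13), Alg genes of protein N-glycosylation (8 members, -1.17), the Ndufb subunits of mitochondrial complex I (9 members, -1.43) and proteasome beta subunits (Psmb, 10 members, -1.35). With the trend removed their medians were -1.01, -0.96, -0.91, -0.85, -0.66 and -0.61. The Ndufa subunits of the same complex (14 members) did not stand low, with a median of -0.53 at the 61.1st percentile as deposited and -0.006 with the trend removed. Except for Rpl and Rps, the medians of the families named here kept their sign under all 3 scalings.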
